A study of Mus musculus with 24 samples.

How the data were processed

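RNA was measured in 24 libraries of cultured mouse CD8+ T cells, each made from 1000 sorted cells by a modified SMART-Seq2 protocol with 11 amplification cycles and read as pairs of 38 nt. Per the labels, naive cells were stimulated with antibodies to CD3 and CD28 at 1 µg/ml each. Day 3 libraries followed 3 days of stimulation, and day 9 libraries followed 3 days of stimulation, 3 days of rest in IL2 at 5 ng/ml and 3 days of restimulation. The groups were taken from the labels: WT or cKO with and without Dex at day 3, and Ctrl, Dex, IL27 and Dex+IL27 in WT cells at day 9, with 3 libraries in each of the 8 groups.

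The estimated counts per gene were deposited by the authors as RSEM gene-level estimates with no normalization. The FPKM values were deposited by the authors from the same RSEM estimates and, per their name, were scaled by TMM across libraries. The submitters name TopHat, RSEM, DESeq and the mm9 genome build, without versions or roles. An mm9 annotation was not used here, and genes are identified by the symbols in the deposited tables. Both tables hold 23366 genes for all 24 libraries, and estimated counts summed to between 14221900 and 19018400 per library. Counts are of amplified reads without molecular identifiers.

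Counts were rounded and tested with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3), two-sided, with TMM scaling and a prior count of 0.125. The low-count filter was filterByExpr by group (minimum count 10, minimum total 15), which left 11967 genes at day 3, 12320 at day 9 and 12666 in the fit of all 24 libraries. The 12 libraries of a day were fitted together with 1 mean per group. The 12 comparisons were contrasts of these means: 9 between 2 groups, the genotype by Dex and Dex by IL27 interactions, and the Dex effect at day 9 minus that at day 3 in 1 fit of all 24 libraries. Benjamini-Hochberg adjusted p under 0.05 counted as a call, written as passing the test. Leave-one-out fits that left a group with 2 libraries pooled their spread with the other groups.

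The comparisons, tests, 18 gene lists (313 members, 2 found under an older symbol), naming rule and alternatives were set before the data were examined, except those named as later. Lists covered glucocorticoid response, inhibitory receptors, transcription factors of effector and dysfunctional cells, naive and memory genes, cytokines and chemokines, cytotoxic granules, activation and NF-kB, cell cycle, trafficking and adhesion, cholesterol synthesis, glycolysis and hypoxia, apoptosis, and markers of B cells, myeloid and dendritic cells, CD4 T cells, NK cells, and erythroid cells and platelets, and 1 further list that is not reported here. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Named genes were 14 fixed genes, up to 4 members of each list with the lowest p, and the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM in 1 group and libraries that did not overlap between groups (the last condition left out for interactions). For genes at 0 counts in a group the fold was taken against a floor of 3 counts over the group and given with the lower limit of its exact 95% counting interval. With 1 to 3 counts the ratio has an exact 95% counting interval.

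Alternatives were size factors of DESeq2 in edgeR, no low-count filter, the Wald test of DESeq2 1.42.0, limma on log2 of FPKM plus 1 (genes with a mean of at least 1 FPKM in a group), a pseudocount of 0.1 or no filter there, only the 2 groups compared, all 24 libraries in 1 fit, the replicate number as a block, and each library left out in turn. Scaling by library totals only, leaving out Rn45s, and giving Dex and IL27 different Ctrl libraries in their overlap, with the spread pooled over the day 9 groups, were added after seeing the data. The fits were tested on simulated data: of genes changed 4-fold, edgeR recovered 97.9% in the day 3 Dex comparison, 85.4% in the genotype by Dex interaction, 87.5% in the day 9 Dex comparison and 77.1% in the Dex by IL27 interaction. In the same order it recovered 79%, 66%, 76.8% and 66.7% of genes changed 2-fold and 66%, 42%, 56% and 34% of genes changed 1.5-fold. Of the simulated calls in these fits 6.47%, 5.88%, 3.31% and 3.23% were false. The simulated data left 11648 of 11846 genes unchanged at day 3 and 11951 of 12148 at day 9. In the real data 6850 of 12320 genes passed with Dex at day 9, so these shares may not carry over to that day. Overlap of the Dex and IL27 responses was set beside 20 simulations of unchanged groups with shared controls. The effect of day alone was not tested, since the leading letter of the sample titles (D or E) and culture history run with it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.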

Results

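RNA was sequenced from mouse CD8+ T cells that had been sorted as naive cells and activated in culture with antibodies to CD3 and CD28. The 24 libraries form 8 groups of 3. At day 3, WT cells and cells lacking the glucocorticoid receptor gene Nr3c1 through a CD8-lineage Cre (cKO) were cultured without (Ctrl) or with 10 nM dexamethasone (Dex), a synthetic glucocorticoid. At day 9, after 3 days of rest and 3 days of restimulation, WT cells had been cultured without additions (Ctrl), with Dex, with 25 ng/ml of the cytokine IL27, or with both (Dex+IL27). The comparisons ask what glucocorticoid signalling and IL27 each do to activated CD8+ T cells, and whether the Dex response needs the receptor in these cells. Estimated counts summed to between 14221900 and 19018400 per library. Changes are log2 fold changes ± SE from edgeR with 3 libraries per group, and levels are mean CPM ± SD with n = 3.

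At day 3 the leading principal component held 22.4% of the variance, and the 3 WT Dex libraries lay between -29.7 and -26.4 on it while the other 9 libraries lay between 3.38 and 13.6. At day 9 the leading component held 53.4%, with Ctrl libraries between -73.6 and -70.8 and Dex+IL27 libraries between 48.9 and 51.3. The next component of day 9 held 15.6% and set Dex libraries (-38.4 to -37.5) apart from IL27 libraries (26.8 to 34.4). Rn45s, the ribosomal RNA precursor, took a share of counts that moved with the day 9 groups: 9.11% ± 0.15 in Ctrl, 14.6% ± 0.49 in Dex, 14.1% ± 0.41 in IL27 and 16.04% ± 0.31 in Dex+IL27 (SD, n = 3). At day 3 its share was 11.1% ± 0.57 in WT Ctrl, 12.4% ± 0.45 in WT Dex, 12.8% ± 0.29 in cKO Ctrl and 12.5% ± 0.79 in cKO Dex. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these samples. Of 536 results of named genes past the test in comparisons of 2 groups, 535 had all 3 libraries of 1 group above all 3 of the other, which chance gives for 10% of genes and which the naming rule asked for in part; the exception was Cd4 in Dex+IL27 against Dex.

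**Figure D1:**
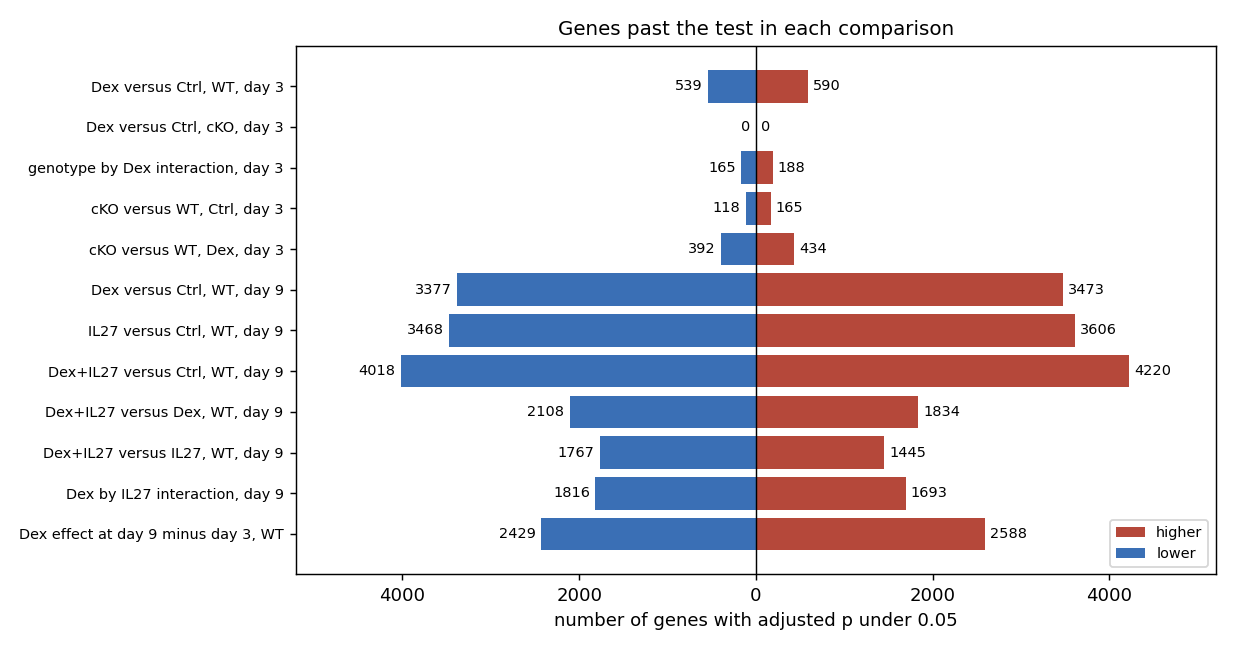
Number of genes with adjusted p under 0.05 in each of the 12 comparisons (x axis, number of genes), higher to the right and lower to the left. No gene passed with Dex in cKO cells, against 590 higher and 539 lower in WT cells at day 3.

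Nr3c1, the targeted gene, was lower in every cKO library than in every WT library of day 3. Its CPM ranged from 15.2 to 22.1 in the 6 WT libraries and from 5.49 to 8.46 in the 6 cKO libraries. The change was -1.14 ± 0.15, adjusted p = 8.6e-04 without Dex and -1.65 ± 0.15, adjusted p = 1.2e-06 with Dex. The cKO level was 45.4% of WT without Dex and 31.7% with Dex. The labels do not name the deleted exon, so reads from the rest of the gene may remain in these gene-level counts.

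At day 3, Dex raised known glucocorticoid targets and lowered inflammatory cytokines in WT cells. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose from 59.2 ± 6.81 to 196 ± 17.9 CPM (1.73 ± 0.11, adjusted p = 8.4e-09). Fkbp5, a co-chaperone of the receptor, rose by 1.09 ± 0.10 and the metallothionein Mt1 by 2.12 ± 0.13. Ifng, which encodes interferon gamma, fell from 248 ± 43.2 to 6.71 ± 5.03 CPM (-5.22 ± 0.29, adjusted p = 2.1e-09). In all, 1129 of 11967 genes changed, 590 up and 539 down, of which 132 rose and 50 fell at least 2-fold. With library totals only, a scaling chosen after seeing the data, 506 went up and 690 down. Among the largest rises were Plaur, the urokinase receptor (3.20 ± 0.09), Tgfb3, a cytokine of the TGF-beta family (3.67 ± 0.29), Lrp1, an endocytic receptor (3.05 ± 0.17), and Ramp3 (2.53 ± 0.23).

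Of the glucocorticoid response list there were 18 measured members, of which 10 rose, 0 fell and 8 did not pass the test (11 rose and 0 fell adjusted over the list alone); camera adjusted p = 1.4e-22, and adjusted p = 6.7e-05 with an estimated correlation. Il7r, the interleukin 7 receptor, was among those that rose (0.81 ± 0.08). Cytokines and chemokines had 12 measured members, of which 1 rose, 7 fell and 4 did not pass the test (1 rose and 8 fell adjusted over the list alone); camera adjusted p = 3.0e-16, and adjusted p = 0.00451 with an estimated correlation. The chemokines Xcl1 (-1.73 ± 0.21) and Ccl3 (-1.40 ± 0.18), the lymphotoxin gene Lta (-1.05 ± 0.08) and Tnf (-0.94 ± 0.15) fell. Inhibitory receptors had 15 measured members, of which 2 rose, 2 fell and 11 did not pass the test (2 rose and 3 fell adjusted over the list alone); camera adjusted p = 0.367. Pdcd1, which encodes PD-1, rose from 66.8 ± 6.30 to 155 ± 20.9 CPM (1.22 ± 0.10) and Ctla4 rose by 1.03 ± 0.06, while Cd200 fell (-0.64 ± 0.07). Lag3 (-0.04 ± 0.10, adjusted p = 0.853) and Tigit (-0.02 ± 0.10, adjusted p = 0.942) did not pass the test.

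Transcription factors of effector and dysfunctional cells had 18 measured members, of which 5 rose, 5 fell and 8 did not pass the test (5 rose and 9 fell adjusted over the list alone). Id2 (1.72 ± 0.11), Hif1a (0.76 ± 0.06) and Nfil3 (0.95 ± 0.12) rose, and the T-box factor Eomes fell (-1.90 ± 0.19). Naive and memory genes had 15 measured members, of which 6 rose, 4 fell and 5 did not pass the test (6 rose and 5 fell adjusted over the list alone), with rises of the homing receptor Ccr7 (0.79 ± 0.08) and of Lef1 (0.38 ± 0.06) and a fall of Ltb (-0.77 ± 0.12). Cytotoxic granule genes had 14 measured members, of which 5 rose, 3 fell and 6 did not pass the test (5 rose and 4 fell adjusted over the list alone). Gzmb, which encodes granzyme B, fell (-0.45 ± 0.05, adjusted p = 1.4e-05) and Serpinb9, its inhibitor, rose (0.54 ± 0.06). Gzma, which lies in a family of similar granzymes whose reads may be shared, had 391 counts over the 3 Dex libraries and 1 over the 3 Ctrl libraries, a ratio of 387 (95% counting interval 69.1 to 15331). Activation and NF-kB genes had 24 measured members, of which 6 rose, 6 fell and 12 did not pass the test (6 rose and 7 fell adjusted over the list alone), with the costimulator Icos up (1.09 ± 0.10) and Jun down (-0.67 ± 0.11). The lists of markers of other cells gave 1 call: of 4 measured members of the CD4 T cell list Trat1 fell (-1.76 ± 0.20). This call alone does not show a change in CD4 T cells. None of 2 B cell and 3 myeloid markers passed. Rn45s took 12.4% of counts with Dex and 11.1% in Ctrl.

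These calls came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count fell to 722 without WT_Ctrl replicate 2 and to 691 without WT_Dex replicate 3. Tcf7, a factor of naive and memory cells, fell by 0.23 (adjusted p = 0.0464), but this call ended without 5 of the 6 libraries (all except WT_Dex replicate 2; adjusted p from 0.0578 to 0.207, highest without WT_Dex replicate 3), without a low-count filter (0.0592) and with all 24 libraries in 1 fit (0.403), with adjusted p from 0.0238 to 0.403 over 17 alternatives. Il10, which encodes an anti-inflammatory cytokine, rose by 2.84 ± 0.68 (adjusted p = 0.0117), a call that ended without WT_Ctrl replicate 2 (0.0626), without WT_Dex replicate 3 (0.0512) and in DESeq2 (0.0509), with adjusted p from 5.8e-10 to 0.0626 over 17 alternatives.

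**Figure D2:**
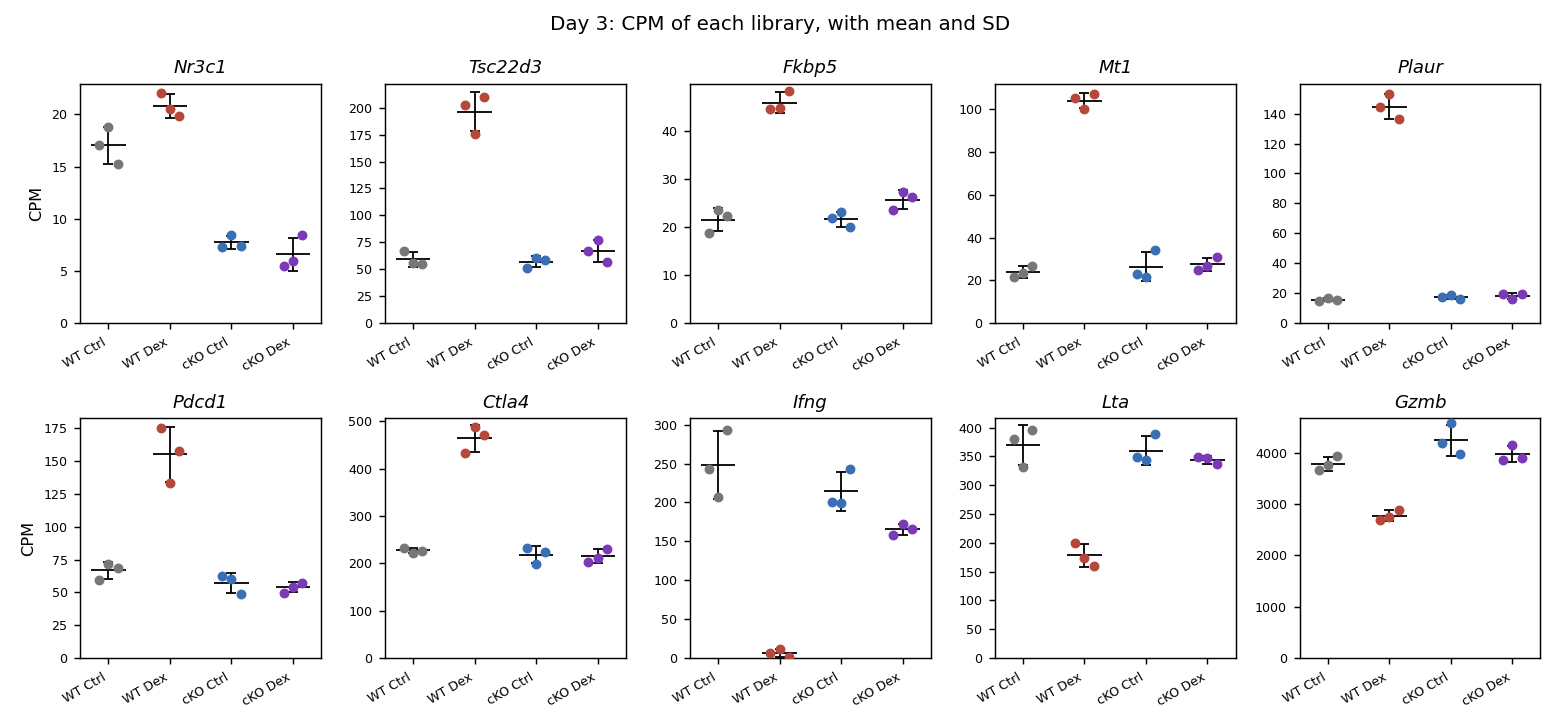
Day 3 levels of 10 genes in CPM (y axes) for the 4 groups on the x axes; points are libraries, horizontal lines means and error bars SDs of 3 libraries. Tsc22d3 had a mean of 196 CPM in WT Dex and of 67.2 CPM in cKO Dex, and Ifng of 6.71 and 165 CPM.

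In cKO cells no gene passed the test at the same dose of Dex. Tsc22d3 was at 56.9 ± 5.04 CPM without and 67.2 ± 10.3 CPM with Dex (0.24 ± 0.11, adjusted p = 1.00). The log2 change of Fkbp5 was 0.25 ± 0.10 and that of Pdcd1 -0.08 ± 0.11. Ifng had 214 ± 24.98 CPM without and 165 ± 7.40 CPM with Dex (-0.37 ± 0.21, adjusted p = 1.00). Of 11967 genes 0 passed in edgeR, DESeq2 or limma with FPKM, and 399 genes had an unadjusted p under 0.05. The glucocorticoid response list had 18 measured members, of which 0 rose, 0 fell and 18 did not pass the test (2 rose and 0 fell adjusted over the list alone), and as a list it lay higher with Dex (camera adjusted p = 0.00592, and adjusted p = 0.0749 with an estimated correlation). Without a low-count filter 26 genes passed, Ifng among them (adjusted p = 2.1e-05), with adjusted p from 2.1e-05 to 1.00 over 17 alternatives for Ifng. With only these 6 libraries, and without cKO_Ctrl replicate 5, 1 gene passed.

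The genotypes differed in their response to Dex when the difference itself was tested, as the WT change minus the cKO change. Plaur (3.12 ± 0.13, adjusted p = 2.5e-10), Mt1 (2.06 ± 0.19), Tsc22d3 (1.49 ± 0.15), Pdcd1 (1.30 ± 0.15), Ctla4 (1.05 ± 0.09), Id2 (1.55 ± 0.15) and Fkbp5 (0.84 ± 0.14) rose more in WT. Ifng (-4.84 ± 0.36, adjusted p = 3.8e-07), Xcl1 (-1.81 ± 0.29), Eomes (-1.71 ± 0.25) and Lta (-0.99 ± 0.11) fell more in WT. The interaction passed for 353 genes, 188 with a higher and 165 with a lower change in WT (173 and 214 with library totals only, chosen after seeing the data). Among glucocorticoid response genes there were 18 measured members, of which 6 went up more, 0 went down more and 12 did not pass the test (6 went up more and 0 went down more adjusted over the list alone); camera adjusted p = 3.5e-14, and adjusted p = 4.3e-04 with an estimated correlation. Cytokines and chemokines had 12 measured members, of which 0 went up more, 6 went down more and 6 did not pass the test (1 went up more and 9 went down more adjusted over the list alone); camera adjusted p = 7.6e-16, and adjusted p = 0.00642 with an estimated correlation. The count of genes was 765 without a low-count filter, 560 in DESeq2, 185 with FPKM in limma without a filter and 213 with all 24 libraries in 1 fit. It was 235 without WT_Ctrl replicate 2 and 224 without WT_Dex replicate 3, and rose to 479 without cKO_Dex replicate 6. Tnf passed (-0.95 ± 0.21, adjusted p = 0.0193) and lost its call without WT_Ctrl replicate 2 (0.0639), WT_Dex replicate 1 (0.0502) or WT_Dex replicate 3 (0.0674), with FPKM in limma without a filter (0.132) or with all 24 libraries in 1 fit (0.0545), with adjusted p from 2.3e-13 to 0.132 over 22 alternatives. Gzmb passed (-0.35 ± 0.07, adjusted p = 0.00921) but not with all 24 libraries in 1 fit (0.0520) or with FPKM without a filter (0.0841), with adjusted p from 1.9e-07 to 0.0841 over 22 alternatives.

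Without added Dex, cKO and WT cells differed in 283 genes. Beside Nr3c1, Podnl1 was higher in cKO cells (15.2 ± 0.194 against 1.58 ± 0.383 CPM; 3.26 ± 0.23, adjusted p = 9.2e-07), as were Rbm45 (1.61 ± 0.15), the integrin gene Itgb7 (1.06 ± 0.13) and the transcription factor Nfil3 (0.98 ± 0.12). Mid1 (-0.89 ± 0.08), Nomo1 (-0.88 ± 0.10) and Bst2 (-0.43 ± 0.06) were lower. Fkbp5 (0.00 ± 0.10, adjusted p = 0.992) and Tsc22d3 (-0.06 ± 0.11, adjusted p = 0.845) did not pass. Of these genes 165 were higher and 118 lower in cKO cells. Rn45s took 12.8% of counts in cKO and 11.1% in WT cells. Cytokines and chemokines had 12 measured members, of which 0 lay higher, 2 lay lower and 10 did not pass the test (0 lay higher and 6 lay lower adjusted over the list alone); camera adjusted p = 1.4e-06, and adjusted p = 0.106 with an estimated correlation. Glycolysis and hypoxia genes had 20 measured members, of which 1 lay higher, 0 lay lower and 19 did not pass the test (7 lay higher and 0 lay lower adjusted over the list alone); camera adjusted p = 0.00197, and adjusted p = 0.362 with an estimated correlation. Trafficking and adhesion genes had 18 measured members, of which 2 lay higher, 0 lay lower and 16 did not pass the test (2 lay higher and 0 lay lower adjusted over the list alone); camera adjusted p = 0.0110, and adjusted p = 0.106 with an estimated correlation. With library totals only, a scaling chosen after seeing the data, 35.3% of 397 calls were higher, against 58.3% with TMM. The count was 793 without a low-count filter, 540 in DESeq2, 101 with FPKM in limma without a filter and 129 with all 24 libraries in 1 fit. It was 74, 63, 88, 177 and 89 without WT_Ctrl replicates 1 and 2 and cKO_Ctrl replicates 4, 5 and 6, in that order. Without WT_Ctrl replicate 3 it rose to 364.

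With Dex in both cultures, cKO cells had more Ifng and Lta and fewer glucocorticoid target transcripts than WT cells. Ifng was 165 ± 7.40 CPM in cKO and 6.71 ± 5.03 CPM in WT (4.63 ± 0.29, adjusted p = 1.6e-08), Lta was higher by 0.95 ± 0.08, Eomes by 2.12 ± 0.19 and Gzmb by 0.52 ± 0.05. Plaur (-2.97 ± 0.09), Ramp3 (-2.86 ± 0.24), Mt1 (-1.92 ± 0.13), Tsc22d3 (-1.55 ± 0.11), Pdcd1 (-1.53 ± 0.11), Ctla4 (-1.11 ± 0.07) and Fkbp5 (-0.84 ± 0.10) were lower. In all 826 genes passed, 434 higher and 392 lower (357 and 403 with library totals only). The glucocorticoid response list had 18 measured members, of which 0 lay higher, 10 lay lower and 8 did not pass the test (0 lay higher and 12 lay lower adjusted over the list alone); camera adjusted p = 4.4e-17, and adjusted p = 2.0e-04 with an estimated correlation. For cytokines and chemokines there were 12 measured members, of which 4 lay higher, 1 lay lower and 7 did not pass the test (5 lay higher and 1 lay lower adjusted over the list alone); camera adjusted p = 7.7e-07, and adjusted p = 0.0784 with an estimated correlation. Cholesterol synthesis genes had 18 measured members, of which 6 lay higher, 0 lay lower and 12 did not pass the test (6 lay higher and 0 lay lower adjusted over the list alone); camera adjusted p = 7.7e-07, and adjusted p = 0.142 with an estimated correlation. They include Fdps, which encodes farnesyl diphosphate synthase (0.35 ± 0.05). The count was 484, 532, 534 and 497 without WT_Dex replicates 1 and 2 and cKO_Dex replicates 4 and 5, in that order. It rose to 1186 without cKO_Dex replicate 6. Tcf7 was higher (0.41 ± 0.07, adjusted p = 9.7e-04) except with all 24 libraries in 1 fit (0.117), with adjusted p from 2.6e-06 to 0.117 over 16 alternatives. Tnf (0.61 ± 0.15, adjusted p = 0.0206) lost its call without WT_Dex replicate 1 (0.0752), WT_Dex replicate 3 (0.113) or cKO_Dex replicate 4 (0.132), with FPKM in limma without a filter (0.123) or with all 24 libraries in 1 fit (0.0514), with adjusted p from 6.8e-11 to 0.132 over 16 alternatives. Il10 (-2.78 ± 0.67, adjusted p = 0.0157) lost it without WT_Dex replicates 2 (0.0607) or 3 (0.0590) or cKO_Dex replicate 4 (0.0617) or in DESeq2 (0.0647), with adjusted p from 8.3e-10 to 0.0647 over 16 alternatives.

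At day 9, Dex changed 6850 of 12320 genes tested in WT cells, with Tsc22d3, Il10, Lag3 and Pdcd1 up and Ifng and Rrm2 down. Tsc22d3 rose from 19.95 ± 2.49 to 431 ± 48.8 CPM (4.43 ± 0.12, adjusted p = 5.9e-12) and Il10 from 0.796 ± 0.526 to 96.3 ± 7.96 CPM (6.93 ± 0.29, adjusted p = 4.1e-10). Ifng fell from 973 ± 183 to 14.8 ± 9.35 CPM (-6.04 ± 0.52, adjusted p = 2.3e-07), and Rrm2, a subunit of ribonucleotide reductase, from 570.2 ± 22.4 to 144 ± 12.7 CPM (-1.98 ± 0.08). Of the changed genes 3473 went up and 3377 down, of which 1195 rose and 678 fell at least 2-fold (in all 3197 up and 3689 down with library totals only). Sema3a, a secreted guidance factor (6.38 ± 0.26), Tgfb3 (6.29 ± 0.48) and Enpp2 (5.36 ± 0.28) were among the largest rises. Klra6, of a receptor family with similar members, had 754 counts with Dex and 0 without, at least 284-fold higher. Gzmd, a granzyme with similar copies, had 0 counts with Dex and 745 without, 219.9-fold lower against that floor (lower limit 178). Nr3c1 itself rose from 15.2 ± 0.631 to 31.2 ± 0.580 CPM (1.04 ± 0.09).

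Glucocorticoid response genes had 18 measured members, of which 15 rose, 0 fell and 3 did not pass the test (15 rose and 0 fell adjusted over the list alone); camera adjusted p = 2.7e-12, and adjusted p = 0.0129 with an estimated correlation. Fkbp5 (1.78 ± 0.10), Txnip (2.70 ± 0.15) and Il7r (1.40 ± 0.12) were among them. Inhibitory receptors had 18 measured members, of which 12 rose, 4 fell and 2 did not pass the test (12 rose and 4 fell adjusted over the list alone); camera adjusted p = 0.0145, and adjusted p = 0.0994 with an estimated correlation. Lag3 rose from 147 ± 14.5 to 323 ± 13.0 CPM (1.14 ± 0.10), Pdcd1 by 0.99 ± 0.13, Ctla4 by 1.05 ± 0.07, Tigit by 0.54 ± 0.08 and Nt5e, the ectonucleotidase CD73, by 2.32 ± 0.20. Havcr2, which encodes TIM-3, rose by 0.60 ± 0.20 (adjusted p = 0.0194), a call that ended without WT_Ctrl replicate 3 (0.0779), without WT_Dex replicate 3 (0.0687) or with FPKM in limma without a filter (0.0514), with adjusted p from 1.7e-05 to 0.0779 over 17 alternatives. Cd200 fell (-1.88 ± 0.20). Cytokines and chemokines had 18 measured members, of which 2 rose, 14 fell and 2 did not pass the test (2 rose and 14 fell adjusted over the list alone); camera adjusted p = 4.0e-05, and adjusted p = 0.291 with an estimated correlation. Tnf (-2.62 ± 0.20), Lta (-2.59 ± 0.18), Xcl1 (-3.48 ± 0.27) and Il2, the T cell growth factor (-7.05 ± 1.06), fell.

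Cell cycle genes had 24 measured members, of which 0 rose, 20 fell and 4 did not pass the test (0 rose and 20 fell adjusted over the list alone); camera adjusted p = 1.4e-11, and adjusted p = 0.0994 with an estimated correlation. Pcna, the sliding clamp of DNA polymerase (-1.36 ± 0.07), Tyms, thymidylate synthase (-1.84 ± 0.10), and Ccne1 (-1.24 ± 0.07) fell. Cytotoxic granule genes had 17 measured members, of which 6 rose, 8 fell and 3 did not pass the test (6 rose and 8 fell adjusted over the list alone); camera adjusted p = 0.331. Gzmb fell (-1.36 ± 0.07) with Prf1, the pore-forming perforin (-1.54 ± 0.13), while Gzma (3.96 ± 0.33) and Serpinb6b (1.70 ± 0.13) rose. Activation and NF-kB genes had 23 measured members, of which 10 rose, 7 fell and 6 did not pass the test (10 rose and 7 fell adjusted over the list alone), with Icos (2.12 ± 0.11) and Tnfrsf18 (1.44 ± 0.07) up. Transcription factors of effector and dysfunctional cells had 19 measured members, of which 6 rose, 7 fell and 6 did not pass the test (6 rose and 7 fell adjusted over the list alone), with Nfil3 (1.49 ± 0.16) and Gata3 (0.95 ± 0.13) up. Tcf7 (-0.14 ± 0.22, adjusted p = 0.619) and Prdm1 (0.08 ± 0.21, adjusted p = 0.776) did not pass. Of 6 measured myeloid and dendritic markers 3 rose, among them Cd68 from 2.31 ± 0.884 to 9.92 ± 1.42 CPM, while neither of 2 B cell markers nor of 2 NK cell markers passed. Rn45s took 14.6% of counts with Dex and 9.11% in Ctrl.

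IL27 alone lowered every measured gene of the cell cycle list at day 9 and raised Lag3, Tigit and Entpd1. Rrm2 fell to 98.7 ± 4.55 CPM (-2.53 ± 0.08, adjusted p = 6.5e-11), with Mcm5, a subunit of the replicative helicase (-1.64 ± 0.08), and Pcna (-1.56 ± 0.07). Lag3 rose to 396 ± 63.4 CPM (1.43 ± 0.10, adjusted p = 5.1e-08), Entpd1, the ectonucleotidase CD39, by 1.99 ± 0.12 and Tigit by 0.56 ± 0.08, while Pdcd1 fell to 68.5 ± 9.13 CPM (-0.79 ± 0.13). In all 7074 genes passed, 3606 up and 3468 down, of which 1277 rose and 817 fell at least 2-fold (in all 3263 up and 3807 down with library totals only). The integrin gene Itga7 (6.39 ± 0.80), Stac2 (5.99 ± 0.41), Muc2, a mucin (4.52 ± 0.38), and Serpinf1 (4.44 ± 0.15) were among the largest rises.

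Cell cycle genes had 24 measured members, of which 0 rose, 24 fell and 0 did not pass the test (0 rose and 24 fell adjusted over the list alone); camera adjusted p = 2.5e-27, and adjusted p = 0.0337 with an estimated correlation. The glucocorticoid response list had 18 measured members, of which 13 rose, 0 fell and 5 did not pass the test (13 rose and 0 fell adjusted over the list alone); camera adjusted p = 2.7e-05, and adjusted p = 0.114 with an estimated correlation. Tsc22d3 rose to 103 ± 12.7 CPM (2.36 ± 0.11) and Txnip by 2.49 ± 0.15, whereas Fkbp5 did not pass (-0.01 ± 0.10, adjusted p = 0.946). Inhibitory receptors had 18 measured members, of which 7 rose, 5 fell and 6 did not pass the test (7 rose and 5 fell adjusted over the list alone); camera adjusted p = 0.296. Cytokines and chemokines had 18 measured members, of which 2 rose, 13 fell and 3 did not pass the test (2 rose and 13 fell adjusted over the list alone); camera adjusted p = 0.00383, and adjusted p = 0.446 with an estimated correlation. Ifng (-2.73 ± 0.43), Tnf (-1.70 ± 0.19), Lta (-2.09 ± 0.17) and Xcl1 (-3.04 ± 0.26) fell, and Il10 rose (3.27 ± 0.33). Ifng was at 58.0 CPM in WT_IL27 replicate 1 and at 187 and 195 CPM in replicates 2 and 3, against 831 to 1180 CPM in Ctrl. Gzmb (-0.80 ± 0.07) and Prf1 (-1.03 ± 0.13) fell among cytotoxic granule genes, which had 17 measured members, of which 7 rose, 7 fell and 3 did not pass the test (7 rose and 7 fell adjusted over the list alone). Of 6 myeloid and dendritic markers 4 rose, Cd68 by 2.41 ± 0.21, and of 2 B cell markers Ebf1 rose (1.59 ± 0.18). Rn45s took 14.1% of counts with IL27 and 9.11% in Ctrl.

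By a chi-square of the counts per gene, WT_IL27 replicate 1 differed from replicates 2 (26.9) and 3 (16.1) more than these from each other (6.80). Some calls at IL27 were fragile. Tcf7 fell (-0.68 ± 0.23, adjusted p = 0.0185) but not past the test without WT_Ctrl replicate 3 (0.0780) or WT_IL27 replicates 1 (0.0566) or 3 (0.0653), with adjusted p from 1.4e-04 to 0.0780 over 17 alternatives. Prdm1, which encodes BLIMP-1, rose (0.59 ± 0.21, adjusted p = 0.0227) but not without WT_Ctrl replicate 1 (0.0995) or WT_IL27 replicate 1 (0.116) or with FPKM in limma without a filter (0.108), with adjusted p from 0.00154 to 0.116 over 17 alternatives. Il2 fell (-4.43 ± 0.80, adjusted p = 3.8e-04) except in DESeq2 (0.0964), with adjusted p from 4.2e-22 to 0.0964 over 17 alternatives. Nr3c1 had 0.24 ± 0.09 (adjusted p = 0.0403), a call lost without any 1 of the 6 libraries (0.0533 to 0.129) and in 9 other settings (0.0519 to 0.187), with adjusted p from 0.0428 to 0.187 over 17 alternatives.

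The responses to Dex and IL27 at day 9 overlapped. Genes higher in both numbered 2694 and genes lower in both 2701, where independent lists of these sizes would share 1017 and 951; 76 and 65 genes went opposite ways. Tsc22d3, Txnip, Il7r, Il10, Lag3, Tigit and Nfil3 were among the genes higher in both, and Ifng, Tnf, Lta, Xcl1, Gzmb, Prf1, Rrm2 and Pcna among those lower in both. Pdcd1 rose with Dex and fell with IL27. Across genes, which are not independent replicates, the log2 changes correlated at 0.71 with a covariance of 0.634. Both comparisons use the same 3 Ctrl libraries: 20 simulations of unchanged groups against shared controls gave a correlation of 0.49 and a covariance of 0.0408, which leaves a difference of 0.593. A split of the controls, 1 Ctrl library for 1 agent and the others for the other in all 6 ways, was added after seeing the data. With no control library shared, 1880 to 1950 genes were higher in both and 2059 to 2130 lower in both, where independent lists would share at most 661 and 670. The correlation was 0.561 to 0.611 and the covariance 0.607 to 0.640 (a lone library is assumed to vary like the other groups). The split, like the simulations, deals only with the spread of single libraries. A shift common to all 3 Ctrl libraries would still enter both comparisons.

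Cells given both Dex and IL27 differed most from Ctrl by the number of genes of the 3 day 9 treatments. Tsc22d3 reached 796 ± 27.0 CPM (5.32 ± 0.12, adjusted p = 7.1e-13), Lag3 636 ± 54.0 CPM (2.11 ± 0.10), Tigit 280.0 ± 28.3 CPM (1.77 ± 0.08), Havcr2 58.7 ± 4.41 CPM (0.93 ± 0.20) and Prdm1 29.6 ± 5.89 CPM (1.60 ± 0.20). Tcf7 fell to 4.67 ± 2.36 CPM (-2.18 ± 0.25, adjusted p = 1.7e-06) and Rrm2 to 60.7 ± 5.74 CPM (-3.23 ± 0.09). Maf, a transcription factor, had 822 counts with both and 3 in Ctrl, a ratio of 293 (95% counting interval 100.01 to 1425). In all 8238 genes passed, 4220 up and 4018 down, of which 1921 rose and 1577 fell at least 2-fold (in all 3639 up and 4591 down with library totals only). Il2 was at 0 counts against 801 in Ctrl, 249-fold lower against the floor of 3 counts (lower 95% counting limit 202). The chemokine Ccl1 was at 0 against 902, 281-fold lower against that floor (lower limit 228).

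**Figure D3:**
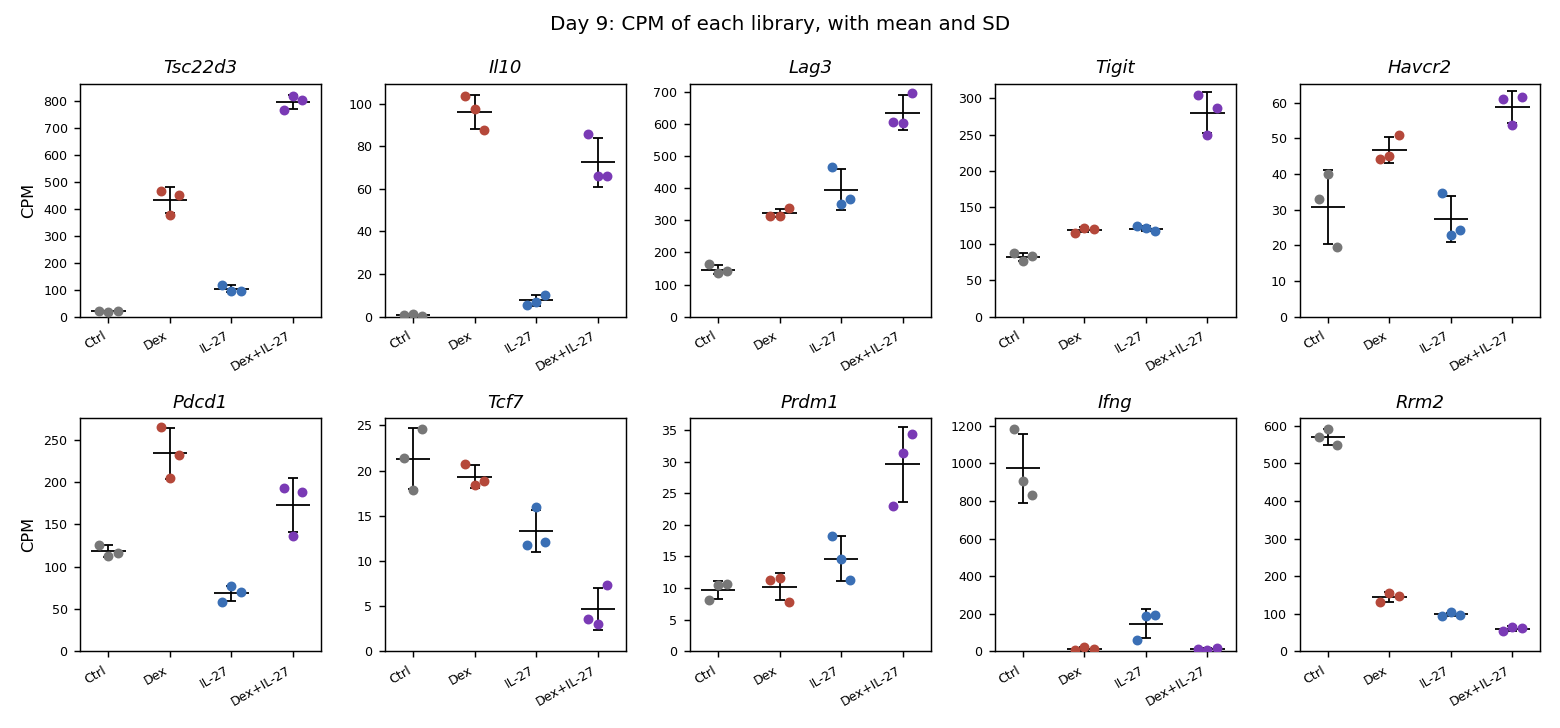
Day 9 levels of 10 genes in CPM (y axes) for the 4 groups on the x axes; points are libraries, horizontal lines means and error bars SDs of 3 libraries. The mean of Lag3 was 147 CPM in Ctrl and 636 CPM with Dex+IL27, and that of Ifng 973 and 12.1 CPM.

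For glucocorticoid response genes there were 18 measured members, of which 15 rose, 0 fell and 3 did not pass the test (15 rose and 0 fell adjusted over the list alone); camera adjusted p = 1.1e-10, and adjusted p = 0.0262 with an estimated correlation. Fkbp5 rose by 1.86 ± 0.10 and Nr3c1 by 1.02 ± 0.09. Cell cycle genes had 24 measured members, of which 0 rose, 24 fell and 0 did not pass the test (0 rose and 24 fell adjusted over the list alone); camera adjusted p = 1.0e-21, and adjusted p = 0.0396 with an estimated correlation. Inhibitory receptors had 18 measured members, of which 9 rose, 5 fell and 4 did not pass the test (9 rose and 5 fell adjusted over the list alone); camera adjusted p = 0.397. Pdcd1 (0.55 ± 0.13) and Entpd1 (1.94 ± 0.12) rose, and Lilrb4, whose reads may be shared with a close copy, fell (-1.61 ± 0.11). Cytokines and chemokines had 18 measured members, of which 3 rose, 14 fell and 1 did not pass the test (3 rose and 14 fell adjusted over the list alone); camera adjusted p = 0.00670, and adjusted p = 0.535 with an estimated correlation. Ifng (-6.32 ± 0.53), Tnf (-3.89 ± 0.21) and Lta (-3.83 ± 0.19) fell, and Il10 rose (6.52 ± 0.29). Transcription factors of effector and dysfunctional cells had 19 measured members, of which 7 rose, 8 fell and 4 did not pass the test (7 rose and 8 fell adjusted over the list alone), with Nfil3 (2.17 ± 0.16) and Runx3 (1.53 ± 0.12) up and Egr2 down (-3.65 ± 0.39). Gzmb fell (-1.20 ± 0.07). Of 6 myeloid and dendritic markers 3 rose, Itgam to 9.51 ± 1.68 CPM and Cd68 to 14.1 ± 0.685 CPM. Rn45s took 16.04% of counts with both agents.

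Adding IL27 to Dex raised Tigit, Lag3 and Prdm1 and lowered Tcf7. Relative to Dex alone, Tigit rose by 1.23 ± 0.08 (adjusted p = 9.4e-08), Lag3 by 0.98 ± 0.10, Prdm1 by 1.53 ± 0.20 and Tsc22d3 by 0.88 ± 0.10, and Tcf7 fell (-2.04 ± 0.25, adjusted p = 4.7e-05). The chemokine receptor Ccr2 (3.56 ± 0.36), the chemokine Ccl5 (3.13 ± 0.25) and Maf (3.19 ± 0.34) rose, while Lif, a cytokine of the interleukin 6 family (-3.84 ± 0.32), Tnf (-1.27 ± 0.22) and the anti-apoptotic Bcl2 (-1.93 ± 0.11) fell. In all 3942 genes passed, 1834 up and 2108 down. Cell cycle genes had 24 measured members, of which 0 rose, 21 fell and 3 did not pass the test (0 rose and 22 fell adjusted over the list alone); camera adjusted p = 6.5e-24, and adjusted p = 0.0673 with an estimated correlation. Activation and NF-kB genes had 23 measured members, of which 1 rose, 14 fell and 8 did not pass the test (1 rose and 15 fell adjusted over the list alone); camera adjusted p = 6.7e-05, and adjusted p = 0.315 with an estimated correlation. Among these Egr1 (-1.61 ± 0.15) and Nfkb1 (-0.72 ± 0.07) fell. Ifng (-0.28 ± 0.51, adjusted p = 0.715) and Il10 (-0.41 ± 0.18, adjusted p = 0.102) did not pass, although Il10 passed without a low-count filter (0.00355) and with only these 6 libraries (0.00942), with adjusted p from 0.00355 to 0.320 over 17 alternatives. With library totals only, the scaling added after seeing the data, 34.6% of calls were higher, against 46.5% with TMM. Pdcd1 fell (-0.44 ± 0.13, adjusted p = 0.0179) but not without WT_Dex replicate 1 (0.0801) or WT_combo replicate 2 (0.0710), with adjusted p from 2.4e-05 to 0.0801 over 17 alternatives.

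Adding Dex to IL27 raised glucocorticoid targets, Pdcd1 and Tigit, and lowered Ifng. Relative to IL27 alone, Tsc22d3 rose by 2.95 ± 0.11 (adjusted p = 4.7e-10), Fkbp5 by 1.86 ± 0.10, Il10 by 3.25 ± 0.21 and Plaur by 6.81 ± 0.26. Pdcd1 (1.33 ± 0.13), Tigit (1.21 ± 0.08), Havcr2 (1.11 ± 0.20), Ctla4 (1.03 ± 0.07), Prdm1 (1.01 ± 0.20), Nr3c1 (0.77 ± 0.09) and Lag3 (0.68 ± 0.10) rose. Ifng (-3.59 ± 0.48, adjusted p = 1.3e-04), Tnf (-2.19 ± 0.21), Tcf7 (-1.504 ± 0.25) and Gzmb (-0.40 ± 0.07) fell. In all 3212 genes passed, 1445 up and 1767 down. The count rose to 3964 without WT_IL27 replicate 1 and fell to 2161 without WT_IL27 replicate 3. Glucocorticoid response genes here had 18 measured members, of which 11 rose, 0 fell and 7 did not pass the test (11 rose and 0 fell adjusted over the list alone); camera adjusted p = 5.0e-16, and adjusted p = 0.00386 with an estimated correlation. Inhibitory receptors had 18 measured members, of which 6 rose, 5 fell and 7 did not pass the test (6 rose and 6 fell adjusted over the list alone); camera adjusted p = 0.775. Those that fell include Procr (-2.01 ± 0.17) and Lilrb4, whose reads may be shared with a close copy (-1.61 ± 0.11). With library totals only, 33.6% of calls were higher, against 44.99% with TMM.

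On the log2 scale the combined response was smaller than the sum of the 2 single responses for many genes, as tested by the Dex by IL27 interaction (Dex+IL27 minus Dex minus IL27 plus Ctrl). Il10 (-3.68 ± 0.39, adjusted p = 1.6e-05), Txnip (-1.84 ± 0.20), Tsc22d3 (-1.48 ± 0.15) and Tnfrsf18 (-1.58 ± 0.10), which rose with each agent, had negative interactions on that scale. In CPM, Tsc22d3 was at 19.95 ± 2.49 in Ctrl, 431 ± 48.8 with Dex, 103 ± 12.7 with IL27 and 796 ± 27.0 with both, a larger rise than the sum of the single ones, and Lag3 also rose by more than the sum in CPM. Rrm2 (1.28 ± 0.11, adjusted p = 3.6e-06), Tyms (1.58 ± 0.15), Prf1 (1.94 ± 0.19), Gzmb (0.95 ± 0.10) and Ifng (2.45 ± 0.66), which fell with each, had positive interactions. Tigit went the other way, with a rise beyond the sum (0.67 ± 0.11, adjusted p = 4.9e-04), and Tcf7 fell beyond the sum (-1.36 ± 0.34, adjusted p = 0.00772). In all 3509 genes passed, 1693 positive and 1816 negative (1594 and 1856 with library totals only). Cell cycle genes had 24 measured members, of which 15 lay above 0, 0 lay below 0 and 9 did not pass the test (15 lay above 0 and 0 lay below 0 adjusted over the list alone); camera adjusted p = 3.8e-09, and adjusted p = 0.171 with an estimated correlation. Activation and NF-kB genes had 23 measured members, of which 3 lay above 0, 12 lay below 0 and 8 did not pass the test (3 lay above 0 and 12 lay below 0 adjusted over the list alone); camera adjusted p = 2.7e-04, and adjusted p = 0.236 with an estimated correlation. Inhibitory receptors had 18 measured members, of which 1 lay above 0, 9 lay below 0 and 8 did not pass the test (3 lay above 0 and 9 lay below 0 adjusted over the list alone); camera adjusted p = 0.00255, and adjusted p = 0.0938 with an estimated correlation.

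Of the genes called in the same direction with both agents, 95.6% had a log2 interaction opposite to that direction, and 2848 of those 5395 genes passed the interaction test that way against 9 the other way. The next named genes passed with less certainty. Lag3 had -0.45 ± 0.14 (adjusted p = 0.0285) but not past the test without WT_Ctrl replicates 2 (0.0856) or 3 (0.0659), WT_Dex replicate 3 (0.0680) or WT_combo replicates 1 (0.0679) or 2 (0.0613) or with FPKM in limma without a filter (0.0711), with adjusted p from 0.00100 to 0.0856 over 22 alternatives. Prdm1 had 0.93 ± 0.29 (adjusted p = 0.0258) but not without WT_Ctrl replicates 2 (0.0569) or 3 (0.0612), WT_Dex replicate 3 (0.0674), WT_IL27 replicate 3 (0.0641) or WT_combo replicates 2 (0.0533) or 3 (0.0657) or with FPKM in limma without a filter (0.0679), with adjusted p from 4.6e-04 to 0.0679 over 22 alternatives.

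The Dex effect in WT cells differed between day 9 and day 3, as tested by the day 9 change minus the day 3 change. Tsc22d3 (2.74 ± 0.16, adjusted p = 3.4e-11), Txnip (2.18 ± 0.18), Lag3 (1.21 ± 0.16), Nt5e (2.18 ± 0.26), Nr3c1 (0.79 ± 0.17), Fkbp5 (0.73 ± 0.14) and Tigit (0.59 ± 0.13) had a higher change at day 9. Rrm2 (-1.94 ± 0.13, adjusted p = 1.4e-10), Pcna (-1.38 ± 0.11), Tnf (-1.65 ± 0.26), Il2 (-6.19 ± 1.31), Gzmb (-0.87 ± 0.10) and Mt1 (-1.41 ± 0.22) had a lower one. Ifng (-0.79 ± 0.65, adjusted p = 0.357) and Pdcd1 (-0.20 ± 0.18, adjusted p = 0.410) did not pass. Ifng passed without a low-count filter (adjusted p = 2.6e-09), with adjusted p from 2.6e-09 to 0.908 over 21 alternatives. In all 5017 of 12666 genes passed, 2588 higher and 2429 lower at day 9 (2283 and 2715 with library totals only). Cell cycle genes had 24 measured members, of which 0 lay higher, 20 lay lower and 4 did not pass the test (0 lay higher and 21 lay lower adjusted over the list alone); camera adjusted p = 4.6e-14, and adjusted p = 0.133 with an estimated correlation. The glucocorticoid response list had 18 measured members, of which 10 lay higher, 2 lay lower and 6 did not pass the test (10 lay higher and 2 lay lower adjusted over the list alone); camera adjusted p = 0.00225, and adjusted p = 0.0950 with an estimated correlation. Il10 had 4.10 ± 0.85 (adjusted p = 4.3e-04), and adjusted p = 0.0504 without WT_Ctrl_Day3 replicate 3, with adjusted p from 4.1e-21 to 0.0504 over 21 alternatives. The days also differ in culture history and in the leading letter of the sample titles, so the day itself was not tested.

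The day 3 and day 9 Dex responses, which share no library, had 401 genes higher in both and 288 lower in both, where independent lists would share 167 and 149; 60 and 80 genes went opposite ways. Tsc22d3, Fkbp5, Il7r, Pdcd1, Ctla4, Icos, Tgfb3 and Irgc1 were among the genes higher on both days, and Ifng, Tnf, Lta, Xcl1, Cd200 and Gzmb among those lower on both. List calls that held at adjusted p under 0.05 with an estimated correlation were the glucocorticoid response list in 6 comparisons, cytokines and chemokines in 2 and cell cycle genes in 2. Intervals and floors given here cover counting error only, since amplified reads without molecular identifiers are not independent molecules.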

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

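The tests of cells that kept the receptor, of glucocorticoids in the medium and of scaling between genotypes, and the breakdown of splits by intact arms, were chosen after the result was seen. Effects of the same treatment differed between groups by a test of the difference itself for 353 genes in the genotype by Dex interaction (edgeR, adjusted p under 0.05), for 3509 genes in the Dex by IL27 interaction and for 5017 genes in the Dex effect at day 9 minus day 3. As many genes came from 11 of 100 splits for the genotype by Dex interaction (highest other 915), 8 of 100 for the Dex by IL27 interaction (highest other 7218) and 6 of 100 for the difference between days (highest other 6091), the real split included. A split that calls more genes than the real one points to a structure of the samples: in each case 24 of the other splits kept the treatment groups of 1 arm intact and mixed the other arm, and the 10, 7 and 5 other splits with as many genes were all among these. The highest count without an intact arm was 0 in all 3. Splits with an intact arm keep the effect of a treatment, so these shares, all above 0.05, neither exclude chance nor speak for it.

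For the comparisons of 2 groups, 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 1129 genes for Dex at day 3 in WT cells, 283 and 826 for genotype without and with Dex, 6850 for Dex, 7074 for IL27 and 8238 for Dex+IL27 at day 9, 3942 for Dex+IL27 against Dex and 3212 for Dex+IL27 against IL27. In each of these 1 of 10 splits, the real one, gave as many, and the highest other was 0, except 1 gene for Dex+IL27 against Dex. For Dex in cKO cells 10 of 10 splits gave as many as the real 0, with a highest other of 4.

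The glucocorticoid response list lay higher with Dex in cKO cells (camera adjusted p = 0.00592, and adjusted p = 0.0749 with an estimated correlation) although none of its members passed the test. If cells that kept the receptor carried all of the Nr3c1 transcript left in the cKO libraries, which was 37.9% of the WT level, the list would answer at about that share. The cKO change was 8.70% (SE 3.67) of the WT change over the 10 members that rose in WT, which argues against that explanation. Over 177 genes outside the list that changed at least 2-fold in WT it was 3.06% (SE 1.90), with 4.51% (SE 1.82) for 127 that rose and -3.38% (SE 4.36) for 50 that fell. A smaller share of cells that kept the receptor and answered like WT cells may remain. It was not told apart from a weak response of the list alone: the values inside and outside the list differ by less than 2 standard errors. That standard error takes the 2 values as independent although both come from the same cKO libraries, so the comparison is only approximate. A response without this receptor stays open, untested.

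Without Dex, 283 genes differed between cKO and WT cells. Flanking DNA of another strain around the targeted gene would place most of them on the chromosome of Nr3c1, which held 2.48% of the called genes and 2.34% of the genes tested, and 1 of 50 neighbours was called. Loss of signalling by glucocorticoids already in the medium would turn most of them opposite to Dex, but 26.5% of 279 genes went opposite to the Dex effect at day 9, which uses other libraries. That effect comes from restimulated cells and had the same sign for 77.0% of the genes called with Dex at day 3. Across all genes the genotype change and the day 9 Dex effect correlated at 0.22, so the signs are not a trait of the called genes alone. Scaling, with Rn45s at a larger share in cKO libraries, would end most calls, but 90.5% were still called with library totals only and 98.9% without Rn45s. The number and balance of calls did depend on scaling: library totals only gave 397 calls, 35.3% of them higher, against 58.3% of 283 with TMM. These values argue against flanking DNA as the whole cause. With the limits given, they also argue against glucocorticoids in the medium and scaling as the whole cause. Separate animals or cultures (numbers 4 to 6 against 1 to 3), the Cre transgene and loss of the receptor before activation stay open, untested.

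At day 9 the combined Dex and IL27 response was smaller than the sum of the single responses on the log2 scale, which was the only scale tested: of 5395 genes called the same way with both agents, 95.6% had an opposing interaction. A counting floor would act on genes that fell, but the share was 96.5% among genes that rose with both and 94.8% among genes that fell. Chance values of the shared Ctrl libraries gave at most 59.4% (mean 58.1%) in 20 simulations with additive effects, in which at most 1 gene passed the interaction test. The simulated libraries varied independently of each other, so a shift common to all 3 Ctrl libraries was not simulated. Such a shift would enter the interaction with the sign opposite to that in both single responses, and stays open, untested. With library totals only and without Rn45s the lower of the shares was 95.2% and the higher 95.8%, which argues against scaling, with the largest Rn45s share in the combination, as the cause. Agents that act on shared targets may give this pattern, which stays a hypothesis, and a shift in the make-up of the cultures stays open; neither was tested, and in CPM some genes, such as Tsc22d3, rose by more than the sum.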

How the results depend on the processing

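Scaling by library totals only, leaving out Rn45s and splitting the controls for the overlap of Dex and IL27 were added after seeing the data; the other settings were planned. With library totals only, the larger number of calls turned from higher to lower in 8 of 12 comparisons. No setting but a left-out library reversed the sign of a called named gene. Counts of genes outside 1.5 times the reported one came from few settings. For Dex in cKO cells (0 genes) they were 26 without a low-count filter, 1 with the replicate block and 1 with only the 2 groups compared. For the genotype by Dex interaction (353) they were 765 without a low-count filter, 560 with DESeq2, 185 with FPKM in limma without a filter and 213 with all 24 libraries in 1 fit. For genotype without Dex (283) the same settings gave 793, 540, 101 and 129. The cause was not tested.

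Leaving out 1 library gave 691 to 1013 genes for Dex at day 3 in WT cells, 0 to 1 in cKO cells, 224 to 479 for the genotype by Dex interaction, 63 to 364 for genotype without Dex and 484 to 1186 with Dex. Those fits have fewer libraries, yet the 479 and 1186 genes came without cKO_Dex replicate 6. By a chi-square of the counts per gene, that library differed from replicates 4 (14.3) and 5 (10.7) more than these from each other (4.42). At day 9 the ranges were 6115 to 6357 for Dex, 6378 to 6904 for IL27, 7722 to 7941 for Dex+IL27, 2780 to 3542 against Dex, 2161 to 3964 against IL27, 2881 to 3571 for the Dex by IL27 interaction and 4524 to 4760 for the difference between days. The overlap of the Dex and IL27 responses ranged from 4855 to 5306 genes (3939 to 4080 with the controls split, added after seeing the data), and Nr3c1 in cKO against WT cells without Dex from -1.21 to -1.06. Klra7, whose reads may be shared with similar copies, had 4.83 in the difference of Dex effects between days, -0.0157 without WT_Ctrl_Day3 replicate 2 (adjusted p = 0.827) and at most 5.63 without WT_Ctrl_Day9 replicate 3.

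The labels share a replicate number between groups without saying what it marks, so the numbers were not read as pairs. Same-number pairs correlated above 0.1 in 8 of 24 cases (-0.293 to 0.503). Some pairs of different numbers also lay above 0.1 (range -0.521 to 0.306), so that count alone does not speak for pairing. Matching their own number best in every other group, which asks for more at day 9, held for 6 of 24 libraries. In cKO cells same-number pairs had 0.278, 0.0673 and 0.375 and other pairs -0.369 to 0.232, so pairing is not excluded there. Dex and IL27 pairs at day 9 had 0.503, 0.390 and 0.0931, against -0.521 to 0.214 for other numbers. Ctrl and Dex+IL27 pairs had -0.157, -0.246 and -0.293. With the replicate block the counts were 1347 for Dex at day 3 in WT cells, 526 for the genotype by Dex interaction, 6752 for Dex, 7028 for IL27 and 8135 for Dex+IL27 at day 9, and 3443 for the Dex by IL27 interaction. Named genes kept their call, or their lack of one, in 7121 of 7446 leave-one-out results (263 weaker, 61 stronger, 1 reversed). They did so in 9878 of 10200 others (177 weaker, 145 stronger). List results were the same in 136 of 181 cases with an estimated correlation, which includes lists called in neither setting. The other 45 were list calls that were lost. With the replicate block 148 of 151 were the same, again with lists called in neither, and 3 gained a call. Depth limits genes at or under the floor of 3 counts over a group.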

Other observations

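No test in this part was chosen after the result was seen. Genes of cell death moved both ways at day 9. Apoptosis genes had 20 measured members, of which 8 rose, 8 fell and 4 did not pass the test (8 rose and 8 fell adjusted over the list alone) with Dex; camera adjusted p = 0.877. Bax, a pore-forming effector of apoptosis, fell (-0.67 ± 0.08), and the death receptor gene Fas (1.44 ± 0.09) and Bcl2 (1.05 ± 0.10) rose. With IL27 there were 20 measured members, of which 6 rose, 5 fell and 9 did not pass the test (6 rose and 5 fell adjusted over the list alone), with Bcl2l11, which encodes the pro-apoptotic BIM (2.21 ± 0.39), and Fas (1.10 ± 0.09) up and Bid down (-0.79 ± 0.10). With both agents Bbc3, a pro-apoptotic BH3-only gene (2.96 ± 0.26), and the anti-apoptotic Mcl1 (1.13 ± 0.08) rose. Trafficking and adhesion genes had 18 measured members, of which 11 rose, 4 fell and 3 did not pass the test (12 rose and 4 fell adjusted over the list alone) with both; camera adjusted p = 0.636. Itga4, an integrin subunit (1.09 ± 0.09), rose, and Cd44, a hyaluronan receptor (-1.90 ± 0.10), Itgb1 (-1.44 ± 0.13) and the chemokine receptor gene Ccr4 (-2.27 ± 0.15) fell. At day 3, Dex raised the chemokine receptor gene Ccr6 (3.10 ± 0.42). Itgae, which encodes the integrin CD103, rose with Dex at day 9 (2.16 ± 0.37).

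Genes of metabolism moved both ways. Cholesterol synthesis genes had 18 measured members, of which 2 rose, 13 fell and 3 did not pass the test (2 rose and 13 fell adjusted over the list alone) with Dex+IL27; camera adjusted p = 0.0253, and adjusted p = 0.468 with an estimated correlation. Idi1, an isomerase of the pathway, fell (-1.79 ± 0.09). At day 3, Dex also lowered Idi1 (-0.31 ± 0.07). Glycolysis and hypoxia genes had 20 measured members, of which 4 rose, 8 fell and 8 did not pass the test (4 rose and 8 fell adjusted over the list alone) with Dex at day 9, with falls of Hk2, a hexokinase (-1.39 ± 0.12), and Ldha, lactate dehydrogenase (-0.86 ± 0.06). With IL27 there were 20 measured members, of which 11 rose, 5 fell and 4 did not pass the test (11 rose and 5 fell adjusted over the list alone), with rises of Aldoa, an aldolase (1.06 ± 0.10), and Pgk1 (0.76 ± 0.08). With Dex+IL27 against Dex there were 20 measured members, of which 8 rose, 1 fell and 11 did not pass the test (8 rose and 1 fell adjusted over the list alone); camera adjusted p = 0.0457, and adjusted p = 0.643 with an estimated correlation.

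The lists of markers of other cells had few measured members, and whether these genes are particular to such cells was not tested. At day 9 the CD4 T cell markers had 4 measured members, of which 1 rose, 2 fell and 1 did not pass the test (1 rose and 2 fell adjusted over the list alone) with Dex, among them a fall of Cd40lg, the ligand of CD40 (-3.30 ± 0.48), and of Trat1 (-2.64 ± 0.44) and a rise of Zbtb7b (1.04 ± 0.13). With IL27, Cd4 itself rose from 0.399 ± 0.0687 to 2.43 ± 0.557 CPM (2.58 ± 0.68) and Cd40lg fell (-3.70 ± 0.49). Of 2 measured NK cell markers Klre1 rose with IL27 (1.17 ± 0.21). None of the erythroid and platelet markers was measured on either day alone, and neither of the 2 measured in the fit of all 24 libraries passed.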
